A study of Homo sapiens with 8 samples.

How the data were processed

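The data are single-colour (Cy3) oligonucleotide expression arrays of NCI-H1299 cells transfected with human DENND2D or with the vector alone, with 4 arrays per group. Each array came as a scanner file, and a table of processed values covered all 8 arrays. Spot intensity values were made with Agilent Feature Extraction 9.1.3.1 and protocol GE1-v5_91_0806, per the file headers. The headers record spatial and multiplicative detrending, no local background subtraction and surrogate values for dim spots, which compress changes near background. The deposited value table was compared with the scanner values: for at least 99.9% of listed probes of each array, each value was the processed signal divided by 1 constant per array, within 0.1%. The deposited table thus holds a linear ratio of each signal to a constant that sets the column median near 1 (1.00 to 1.01), and its empty cells include every probe with no spot well above background. It was used as an alternative only.

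Each array's log2 processed signal was scaled by subtracting its 75th percentile over the 43376 spots that are not controls. Outlier spots were set missing, and spots of a probe were averaged. Of 41000 probes, 36519 were kept because they were well above background on all 4 arrays of at least 1 group. Probes were named through their accession (23680 probes), the file's symbol (2802) or a unique older symbol (1128) in a gene table of assembly GRCh38.p14, and 13390 kept the name in the file. No genome build is given in the sources used here, so this table served only for names and for which genes neighbour each other, and no coordinates are given. For a gene with several probes the brightest was used, which gave 27278 genes, after 4 with too many missing values were left out. Arrays 1 and 2 of a group, which carried 1 labelling reaction, were averaged with avearrays, so that 3 reactions were compared with 3. A linear model with empirical Bayes moderation (lmFit and eBayes in limma 3.58.1, R 4.3.3) gave log2 fold changes, standard errors and p-values, adjusted by Benjamini-Hochberg at 0.05. A second count also required a change of at least 2-fold. Folds are antilogs of fitted log2 differences. Where a gene was well above background on no array of a group, the change is a lower bound.

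The 36 gene lists, with 973 entries and 31 genes in more than 1 list, were written before the data were examined, as were the tests, the rule for named genes and the alternatives, except for spike-in scaling, slide 2 alone and the genes of shifted runs left out. Lists were tested with limma's camera at an inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, adjusted over the 36 lists. Members were counted over all genes tested and adjusted over the list alone. The named genes were DENND2D, the 12 largest rises and 12 largest falls among genes past the threshold with a current symbol, non-overlapping reactions and signal well above background on all 8 arrays, the 5 largest lower bounds each way, and up to 4 members per list with the largest change past the threshold, of which most are printed and the rest are not reported here.

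The replicate numbers are shared by both groups. Deviations of same-numbered reactions from their group means correlated across genes (r = 0.65, 0.35 and 0.31), all above 0.1, so the numbers were taken to pair the reactions. Reaction 1 was hybridised on 1 slide and reactions 2 and 3 on the other in both groups, and reaction 2 of the DENND2D group also correlated with reaction 3 of the vector group (r = 0.35), so the pairing follows the slide at least in part.

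The method was tested on simulated data over the 27278 genes of this comparison with 200 genes changed. It recovered 18% of 50 genes changed 1.2-fold and 64% of those changed 1.5-fold. For 2-fold and 4-fold changes it recovered 66% and 98%, and 10 of its 133 calls were false. The data gave 11175 calls, far more than the genes changed in the simulation, so the adjustment was stricter in the simulation. These rates therefore do not give the share of real changes found in the data. Alternatives were other scalings and background methods, other filters and probe rules, other treatments of replicates and slides, other test settings, the deposited table and each array left out in turn. No array was left out of the main comparison.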

Results

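Gene expression was measured in NCI-H1299, a human non-small cell lung carcinoma line that lacks p53, after transfection with human DENND2D or with the vector alone. DENND2D belongs to the DENN domain proteins, which act as exchange factors for RAB GTPases. Each of the 2 groups was hybridised to 4 single-colour oligonucleotide arrays. The labels state that RNA was labelled in 3 reactions per group and that arrays 1 and 2 of a group carried the same reaction, so each group held 3 labelling reactions (n = 3). On single arrays, 88.6% to 92.3% of the 43376 gene spots were well above background, and the 75th percentile of the signal lay between 1672 and 2034. The number of arrays limits the precision. The labels do not say that the reactions came from separate cultures or clones, so the p-values measure only the spread between these samples, which may be technical.

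The transfected gene was examined first, since it checks the labels. DENND2D was not measurably higher in the arrays labelled DENND2D. Its brighter probe averaged -5.70 ± 0.13 (SD, n = 3 reactions) in those arrays and -4.85 ± 1.04 (SD, n = 3) in the vector arrays, on a log2 scale relative to each array's 75th percentile. The log2 fold change was -0.85 with a 95% confidence interval from -2.12 to 0.42 (SE 0.51, limma adjusted p = 0.254). The signal was close to background throughout: this probe was well above background on 3 of the 4 DENND2D arrays and on all 4 vector arrays. DENND2D replicates 1 and 2, averaged as 1 reaction, read -6.65 (not well above background) and -5.06. The SD of 0.13 does not show this gap. Vector replicate 3, at -3.66, stood apart from the other vector arrays, which lay between -5.59 and -5.40, and without it the log2 fold change was -0.25. The second DENND2D probe was too close to background on arrays of both groups to be tested. Whether either probe lies within the transfected sequence is not known here, so the array does not show which group carried the insert. The groups are therefore called the DENND2D-labelled and the vector-labelled arrays, and every direction below rests on those labels.

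**Figure D1:**
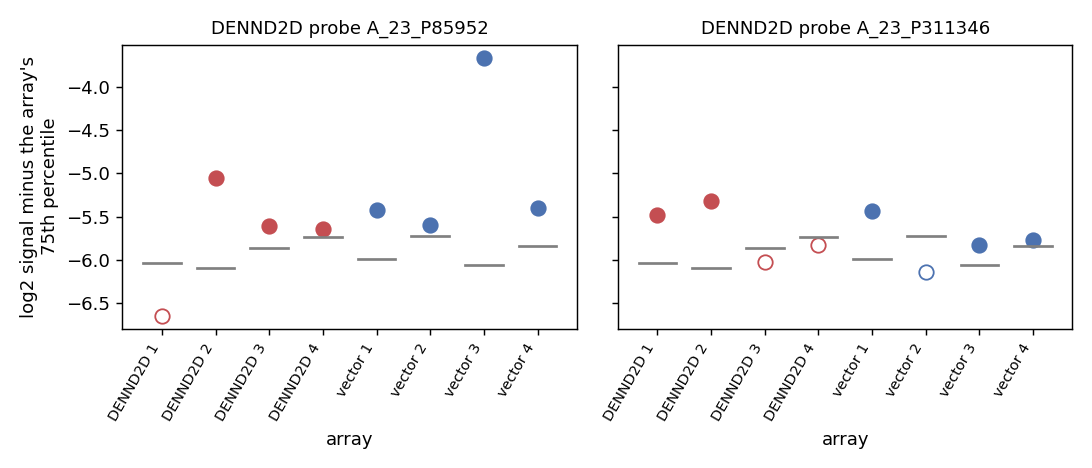
Signal of the 2 DENND2D probes on each of the 8 arrays, as log2 signal minus the array's 75th percentile (y axis), for DENND2D-labelled (red) and vector-labelled (blue) arrays. Grey bars mark the lowest signal well above background on each array and open circles mark values not well above background; vector replicate 3 at -3.66 is the single high value.

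The comparison of the groups asks how the RNA of the cells labelled DENND2D differed from that of the vector cells. By the brightest probe of each gene, FN1, the matrix glycoprotein fibronectin, rose most, 21.1-fold (log2 fold change 4.40, SE 0.04, n = 3 reactions per group, adjusted p = 3.63e-07). IL13RA2, a decoy cytokine receptor, fell most among genes measured on all 8 arrays, 86.6-fold (log2 fold change -6.44, SE 0.04, adjusted p = 2.35e-07). Of 27278 genes tested, 11175 passed an adjusted p of 0.05, 5075 of them higher and 6100 lower in the DENND2D-labelled arrays. Among these, 762 changed at least 2-fold, 228 up and 534 down, and 136 changed at least 4-fold, 21 up and 115 down. Over the 16789 tested genes with a current symbol, 7881 passed, 3931 higher and 3950 lower, and 543 changed at least 2-fold, 178 up and 365 down. The balance of small changes depended on the scaling. With arrays scaled on their median, 5675 genes were higher and 4364 lower, and with arrays scaled on their spike-in spots, 4791 were higher and 3722 lower. At 2-fold or more, falls outnumbered rises under both scalings, with 284 up and 475 down on the median and 281 up and 476 down on the spike-ins. In 52.3% of genes the 3 reactions of one group all lay above those of the other, where chance gives 10%.

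After FN1, the largest rises were in CCNA1, a cyclin best known from germ cells (12.1-fold, log2 SE 0.08), NTN1, the guidance cue netrin (10.95-fold, SE 0.03), and JAG1, a Notch ligand (10.2-fold, SE 0.03). MAP2, a microtubule-associated protein of neurons, rose 7.54-fold, FEZ1, which acts in axon outgrowth, 7.27-fold, and the kinesin gene KIF26B 7.06-fold. SERPINB2, an inhibitor of plasminogen activators, rose 7.02-fold with the widest error of the group (SE 0.22). PLCXD3 (6.21-fold), the ankyrin gene ANK3 (6.19-fold), CSGALNACT1, an enzyme of chondroitin sulfate synthesis (6.07-fold), and the ubiquitin ligase gene RNF128 (5.58-fold) completed the 12 largest rises. After IL13RA2, the largest falls were in RBP7, a retinoid-binding protein (64.2-fold, SE 0.14), C19orf33 (35.8-fold, SE 0.04), CRIP1, a LIM-domain protein (33.2-fold, SE 0.04), and COX7B2, a cytochrome c oxidase subunit found mainly in testis (30.4-fold, SE 0.06). EMILIN2, a matrix glycoprotein, fell 25.6-fold, SUN3, a nuclear envelope protein of spermatids, 24.1-fold, and MGST1, a microsomal glutathione transferase, 23.5-fold. SOHLH2, a transcription factor of germ cells, fell 20.7-fold, the RNA export factor NXF2 20.1-fold, the helicase gene DDX43 17.5-fold, and SLC13A3, a dicarboxylate transporter, 14.4-fold. The limma adjusted p of these 24 genes was at most 0.000298. The size of some changes depended on the probe or on the background. With the mean of a gene's probes, SERPINB2 rose 24.3-fold, more than FN1 at 10.97-fold, while NTN1 rose 3.75-fold and MAP2 3.65-fold, each with 1 of 2 probes past the threshold, FEZ1 rose 4.37-fold and CSGALNACT1 3.93-fold, and C19orf33 and SOHLH2 fell 17.4-fold and 10.5-fold. With normexp background and an offset of 50, which shrinks changes that reach dim signals, IL13RA2 fell 44.6-fold, RBP7 32.6-fold, MGST1 13.2-fold, SOHLH2 12.3-fold, SUN3 10.45-fold, DDX43 9.39-fold and SLC13A3 7.75-fold, and KIF26B rose 3.754-fold.

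**Figure D2:**
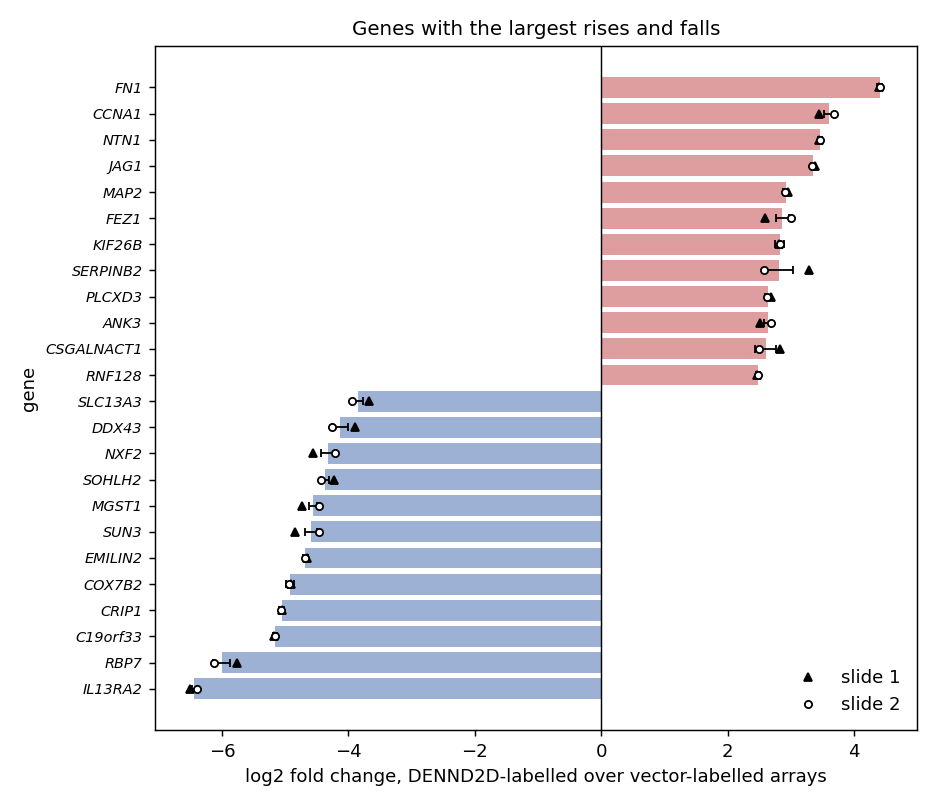
Log2 fold change (x axis) of the 12 genes with the largest rises and the 12 with the largest falls, DENND2D-labelled over vector-labelled arrays. Bars give the fitted value over 3 labelling reactions per group, error bars its standard error, and symbols the value on each of the 2 slides; FN1 reached 4.40 and IL13RA2 -6.44.

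Some genes were well above background on all 4 arrays of one group and on none of the other, so only a lower bound of the change can be given, set against the lowest signal that passed as above background or the dim probe's own signal where higher. There were 29 such genes with a current symbol and a bound above 1, 10 higher and 19 lower in the DENND2D-labelled arrays. PLEK2, a pleckstrin family member, was at least 90.9-fold lower in the DENND2D-labelled arrays, the transcription factor SALL3 at least 10.01-fold, the protocadherin PCDHB6 at least 9.72-fold, the oxidase RNLS at least 8.35-fold and the myosin MYO5C at least 7.26-fold. In the other direction CABCOCO1 was at least 2.98-fold higher and DACT2, an antagonist of Wnt and TGF-beta signalling, at least 2.93-fold. PLD5 was at least 2.89-fold higher and the kinase MAP3K8 at least 2.21-fold. The secreted protein SCUBE2 was 2.29-fold higher. Its bound equals its fitted change, as its signal in the vector-labelled arrays lay above the lowest signal that passed. The adjusted p of these 10 genes was at most 0.00193. These bounds hold for the processed signal only, since with normexp background and an offset of 50 all 10 changes were smaller than their bound, with PLEK2 at 31.5-fold and DACT2 at 2.03-fold.

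The 36 gene lists fixed in advance were tested with camera at a preset inter-gene correlation, and 8 passed an adjusted p of 0.05, 5 upward and 3 downward. None of the 8 passed with a correlation estimated from the residuals, where the lowest adjusted p was 0.182. The estimate was 0.0025 for NF-kB genes and 0.0058 for p53 targets, below the preset 0.01. For the rest of the 8 it was 0.0152 to 0.337. A higher correlation thus does not account for the loss of the NF-kB and p53 lists. With an estimated correlation camera also tests on the residual degrees of freedom alone, which are few here. By fry, which does not compare a list with other genes, 30 lists moved on balance one way and all 36 held changed genes.

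Genes of the unfolded protein response and ATF4 targets gave the clearest rise of any list. Of 29 measured members 23 rose and 3 fell (24 and 5 adjusted over the list alone), with a median log2 fold change of 0.36 and an adjusted p of 9.4e-08 (adjusted p = 0.182 with an estimated correlation). SLC7A11, the cystine transporter, rose 2.49-fold, the stress transcription factor ATF3 2.44-fold, HERPUD1, which acts in degradation at the endoplasmic reticulum, 2.37-fold, and PHGDH, the first enzyme of serine synthesis, 2.10-fold. In the NRF2 list, 11 of 27 rose and 10 fell (12 and 11 adjusted over the list alone, adjusted p = 0.281), and its median of -0.09 differed in sign from its mean of 0.20 and from the test. HMOX1, heme oxygenase, rose 3.48-fold, OSGIN1 2.60-fold and GCLM, a subunit of the enzyme that limits glutathione synthesis, 2.47-fold. Of 26 p53 targets, 11 rose and 3 fell (12 and 3 adjusted over the list alone). Their adjusted p was 0.0446, 0.0648 with the labelling reaction number as a block and 0.379 as an adjusted p with an estimated correlation, and it lay between 0.0525 and 0.0727 when DENND2D replicate 2, 3 or 4 or vector replicate 2 or 4 was left out. PLK2 rose 2.47-fold, GADD45A 2.13-fold and CDKN1A, which encodes the CDK inhibitor p21, 1.92-fold. Of 19 heat shock genes, 8 rose and 3 fell (10 and 4 adjusted over the list alone, adjusted p = 0.19), with DNAJB4 up 1.67-fold. Of 15 metallothioneins and metal-response genes, 3 rose and 9 fell (the same counts adjusted over the list alone, adjusted p = 0.273), with the zinc transporters SLC39A10 and SLC30A1 up 1.56-fold and 1.55-fold and MT1H down 1.27-fold. Of 29 lysosome and autophagy genes, 13 rose and 3 fell (the same adjusted over the list alone). Their adjusted p was 0.0301 (adjusted p = 0.4 with an estimated correlation), and it was 0.0539 without DENND2D replicate 2 and 0.0844 without DENND2D replicate 4. The lysosomal enzymes CTSA and GLA rose 1.72-fold and 1.59-fold and LAMP1 1.56-fold, while CTSZ fell 1.47-fold.

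Inflammatory, antigen presentation and interferon genes moved in different directions. Of 30 NF-kB and cytokine genes, 11 rose and 4 fell (the same adjusted over the list alone, adjusted p = 0.0194, adjusted p = 0.379 with an estimated correlation). The chemokine CXCL1 rose 3.601-fold, BIRC3, an inhibitor of apoptosis, 2.85-fold, and NFKBIA, which retains NF-kB in the cytoplasm, 2.38-fold. Of 16 MHC class I and antigen processing genes, 10 rose and 4 fell (the same adjusted over the list alone, adjusted p = 0.0194, adjusted p = 0.4 with an estimated correlation). HLA-B rose 2.08-fold and HLA-G 1.85-fold, although probes of these related genes may share signal. Of 3 HLA-G probes only 1 passed the threshold, and the mean of its probes gave 1.23-fold. The peptide transporter TAP1 rose 1.84-fold, while the immunoproteasome subunit PSMB8 fell 2.56-fold. With arrays scaled on their median, this list had an adjusted p of 0.0513. Of 38 interferon-stimulated genes, 4 rose and 19 fell (4 and 21 adjusted over the list alone), with a median log2 fold change of -0.26 and an adjusted p of 0.0194 (adjusted p = 0.379 with an estimated correlation). SAMD9 fell 2.96-fold, the ubiquitin-like modifier ISG15 2.67-fold, IFIT3 2.58-fold and PARP9 2.14-fold. With the labelling reaction number as a block the list had an adjusted p of 0.0783, and with the slide as a block 0.0615.

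Ribosomal protein and histone genes fell on balance, and no measured member passed the threshold as higher. Of 38 cytosolic ribosomal protein genes 22 fell (24 adjusted over the list alone), with a median log2 fold change of -0.19 and an adjusted p of 3.18e-05 (adjusted p = 0.421 with an estimated correlation). RPS16 fell 2.14-fold, RPS19 2.11-fold, RPL35 1.76-fold and RPL4 1.45-fold. Of 27 replication-dependent histone genes 17 fell, also over the list alone, with an adjusted p of 0.000423 (adjusted p = 0.379 with an estimated correlation). The linker histones H1-5, H1-3 and H1-4 fell 2.52-fold, 2.16-fold and 1.79-fold. Among 33 G2/M genes 4 rose and 17 fell (6 and 18 adjusted over the list alone, adjusted p = 0.163), with the proliferation marker MKI67 down 1.59-fold, the mitotic cyclin CCNB1 1.57-fold and the phosphatase CDC25C 1.51-fold. With quantile normalization this list passed, at an adjusted p of 0.0187 (adjusted p = 0.689 with the main normalization and an estimated correlation). Of 37 G1/S and replication genes 11 rose and 11 fell (13 and 15 adjusted over the list alone, adjusted p = 0.886), with E2F3 up 1.51-fold. The median of -0.05 and the mean of -0.01 differed in sign from the test. Of 14 CDK inhibitors and quiescence genes 5 rose and 4 fell, also over the list alone (adjusted p = 0.681, with the mean of -0.07 opposite in sign to the median and the test). CDKN2B rose 1.82-fold, while GAS6 and CDKN1C fell 3.70-fold and 2.46-fold.

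Of 32 pro-apoptotic genes 8 rose and 5 fell, also over the list alone (adjusted p = 0.735, with median and mean opposite in sign to the test). PMAIP1, the BH3-only protein NOXA, rose 1.57-fold and BNIP3L 1.40-fold, while BID fell 1.51-fold. With the mean of its probes BID fell 1.31-fold and did not pass (limma adjusted p = 0.222). Of 17 anti-apoptotic genes 5 rose and 5 fell (5 and 6 adjusted over the list alone, adjusted p = 0.559, with the mean opposite in sign to the median and the test). The decoy receptor TNFRSF6B fell 6.90-fold, BIRC2 rose 1.91-fold and BAG1 fell 1.67-fold.

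Adhesion and matrix genes held large changes in both directions. Of 29 matrix proteases and inhibitors 6 rose and 6 fell, also over the list alone (adjusted p = 0.681, with the mean opposite in sign to the median and the test). PLAU, the urokinase plasminogen activator, fell 6.05-fold, while the collagenase MMP1 rose 3.31-fold by the brighter of 2 probes, the only one past the threshold, and 1.73-fold by the mean of both. Of 26 mesenchymal genes 6 rose and 6 fell, also over the list alone (adjusted p = 0.735, with the median opposite in sign to the mean and the test). Beside FN1, SNAI1, a repressor of E-cadherin, rose 1.54-fold, while TGFBI and the collagen COL6A1 fell 2.11-fold and 2.10-fold. COL6A1 had 1 of 2 probes past the threshold and fell 1.66-fold by the mean of both. Of 25 epithelial junction and keratin genes 2 rose and 6 fell (2 and 5 adjusted over the list alone, adjusted p = 0.281). The desmosomal protein DSP fell 5.77-fold and the keratins KRT8 and KRT18 3.99-fold and 1.92-fold, while the tight junction protein CLDN1 rose 3.93-fold. Of 30 integrins and adhesion molecules 10 rose and 6 fell (10 and 7 adjusted over the list alone, adjusted p = 0.344). ITGA3 fell 3.35-fold, and PCDH7 and ITGA4 rose 2.56-fold and 1.93-fold, PCDH7 with 2 of 3 probes past the threshold and 1.62-fold by the mean of its probes.

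Of 25 TGF-beta and SMAD targets 11 rose and 6 fell, also over the list alone (adjusted p = 0.0541, adjusted p = 0.379 with an estimated correlation). The list passed with the labelling reaction number as a block (adjusted p = 0.0465), with the slide as a block (adjusted p = 0.0481) and without vector replicate 3 (adjusted p = 0.0354). ID4 and ID2, inhibitors of basic helix-loop-helix factors, rose 4.50-fold and 2.47-fold, and PMEPA1 rose 3.81-fold. Of 22 Wnt targets 10 rose and 4 fell (10 and 5 adjusted over the list alone, adjusted p = 0.163). The receptors FZD8 and FZD7 rose 3.02-fold and 2.38-fold, while FZD2 and the transcription factor LEF1 fell 2.55-fold each. Of 31 MAPK feedback and immediate early genes 15 rose and 7 fell, also over the list alone (adjusted p = 0.163). The phosphatase DUSP1 rose 2.25-fold, while DUSP5 and KLF2 fell 2.76-fold and 2.57-fold. KLF2 had 1 of 2 probes past the threshold and fell 1.76-fold by the mean of both.

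Of 32 hypoxia and glycolysis genes 16 rose and 9 fell (17 and 9 adjusted over the list alone, adjusted p = 0.0541, adjusted p = 0.4 with an estimated correlation, with 0.0459 without vector replicate 1 and 0.0445 without vector replicate 3). ADM rose 2.02-fold, the oxygen sensor EGLN1 1.83-fold and ANGPTL4 1.82-fold, while the enolase ENO2 fell 2.18-fold. Of 31 nuclear-encoded oxidative phosphorylation subunits 4 rose and 11 fell (5 and 11 adjusted over the list alone, adjusted p = 0.413). UQCRFS1, the Rieske protein, fell 2.26-fold, and the succinate dehydrogenase subunits SDHC and SDHA rose 1.54-fold and 1.42-fold. Of 31 cholesterol and SREBP genes 9 rose and 11 fell (10 and 12 adjusted over the list alone, adjusted p = 0.818, with the mean opposite in sign to the median and the test). SREBF1, the lipogenic SREBP factor, fell 2.19-fold and HMGCS1 rose 1.502-fold.

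Other DENN domain genes and RAB genes moved in both directions. Of 20 other DENN domain genes 3 rose and 5 fell, also over the list alone (adjusted p = 0.715). SBF1 rose 1.57-fold and DENND1A fell 1.51-fold. Of 26 RAB GTPases and their regulators 10 rose and 5 fell, also over the list alone (adjusted p = 0.281). CHML, a RAB escort protein, rose 1.47-fold and RAB27B 1.43-fold, while RAB11A fell 1.37-fold.

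Lineage and other cell-type markers were tested as well. Of 27 neuroendocrine and neuronal genes 9 rose and 3 fell, also over the list alone (adjusted p = 0.163). The neurofilament NEFH rose 3.27-fold, CHGB 2.07-fold and SNAP25 1.90-fold, while ENO2 fell 2.18-fold. Of 22 lung lineage genes 1 rose and 2 fell (1 and 1 adjusted over the list alone, adjusted p = 0.535). The surfactant lipid transporter ABCA3 rose 1.39-fold. TP63 and SOX2 fell 1.93-fold and 1.22-fold, and both lost the threshold under some alternatives. Of 21 cancer-testis antigens 2 rose and 9 fell, also over the list alone (adjusted p = 0.163), with PAGE2 down 8.06-fold (5.30-fold with normexp background), PAGE5 6.82-fold and MAGEA10 2.11-fold and SPANXB1 up 2.04-fold. Among markers of other cells, 1 of 23 blood cell genes fell (0 adjusted over the list alone, adjusted p = 0.433), 4 of 15 endothelial genes fell (also over the list alone, adjusted p = 0.188), with EGFL7 down 1.78-fold, 1 of 13 fibroblast genes rose and 1 fell (also over the list alone, adjusted p = 0.868), and 1 of 15 liver and gut genes fell (also over the list alone, adjusted p = 0.735), SERPINA1 by 1.83-fold. Of 30 KRAB zinc finger genes on chromosome 19, 6 rose and 7 fell, also over the list alone (adjusted p = 0.974, with the mean opposite in sign to the median and the test), with ZNF93 up 1.65-fold and ZNF585A down 1.76-fold.

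**Figure D3:**
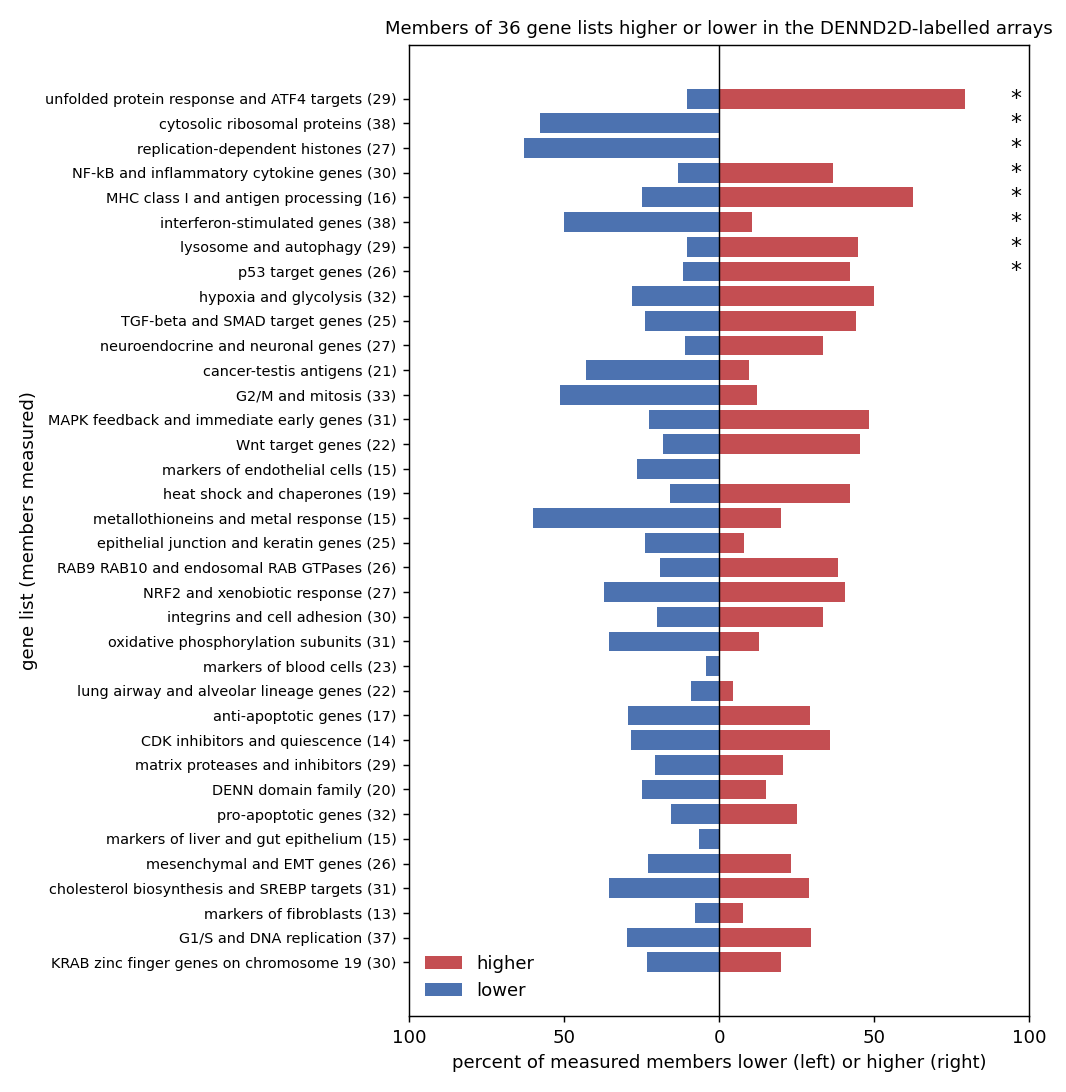
Percent of the measured members of each of the 36 gene lists that were higher (red, right) or lower (blue, left) in the DENND2D-labelled arrays at a limma adjusted p under 0.05, with the number of members measured after each name. Asterisks mark the 8 lists past the camera threshold with a preset correlation; none of them passed with an estimated correlation.

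The arrays lay on 2 slides, each with 2 arrays of either group. Arrays of 1 group differed by a median absolute log2 difference of 0.07 to 0.10 for the same labelling reaction on 1 slide, 0.05 to 0.07 for different reactions on 1 slide and 0.09 to 0.12 across slides. All pairs of the same reaction lay on slide 1, and all pairs of different reactions on 1 slide lay on slide 2. Each group gave 1 pair of either kind, so the kind of replicate cannot be told apart from the slide. Arrays of different groups differed by 0.17 to 0.30. Of 10529 genes past the threshold on slide 2 alone and measured on slide 1, 10200 (96.9%) changed in the same direction on slide 1, where chance gives 50.7%, and so did 782 of the 788 that also changed 2-fold on slide 2. Across genes, which are not independent replicates, the log2 fold changes of the slides correlated with a Pearson r of 0.89 and a Spearman rho of 0.80. With the slide as a block, 13246 genes passed, 764 of them with at least a 2-fold change. Within slide 2, which held 2 reactions per group, 10533 passed, 788 with at least a 2-fold change. Slide 1 held 1 reaction per group and gives no test. For the 8 lists past the threshold, the median log2 fold changes on slides 1 and 2 were 0.38 and 0.37 for unfolded protein response and ATF4 targets, -0.20 and -0.16 for ribosomal proteins, -0.17 and -0.22 for histones, 0.18 and 0.17 for NF-kB genes, 0.34 and 0.33 for MHC class I genes, -0.18 and -0.31 for interferon-stimulated genes, 0.07 and 0.12 for lysosome genes and 0.11 and 0.09 for p53 targets. With the slide as a block their adjusted p was 4.28e-07, 8.63e-05, 0.000857, 0.0127, 0.0351, 0.0615, 0.0351 and 0.0481 in that order. DENND2D-labelled arrays sat at positions 1 and 3 of a slide and vector-labelled arrays at positions 2 and 4, so position and group cannot be told apart.

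Neighbouring genes moved together. Over 16731 genes placed in the order of the GRCh38.p14 gene table, log2 fold changes of adjacent genes had a Spearman correlation of 0.23, against at most 0.03 in 200 shuffles of the order. In runs of 25 consecutive measured genes, 9 runs had a median on slide 1 at least 0.4 below that of all genes, 6 of them on chromosome 19 and 3 on chromosome 9. On slide 2 their medians were -0.79 from ZNF254 to PEPD, -0.71 from GMFG to CCNP and -0.69 from TXN to HDHD3, the lowest of the 9. Of the 225 genes in these runs 171 passed the threshold as lower, 1 as higher and 53 did not pass. Of the 365 placed genes that fell at least 2-fold, 55 lay in these runs. The runs were chosen on slide 1, and its values also enter these calls. Part of both counts thus follows from the choice, and only the slide 2 values are free of it. On chromosome 19, C19orf33, UQCRFS1, RPS16, ZNF585A, ZNF571 and ZNF420 lay in low runs. A run on chromosome 2 with FN1 and MAP2 and a run on chromosome 20 with JAG1, CHGB and SNAP25 had medians of 0.40 and 0.50 on slide 2. On slide 1, where they were chosen, these medians were 0.460 and 0.479, barely above the highest run of shuffled genes, 0.458. The low runs lay at -0.837 to -0.401 on slide 1, and the lowest run of shuffled genes at -0.385.

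**Figure D4:**
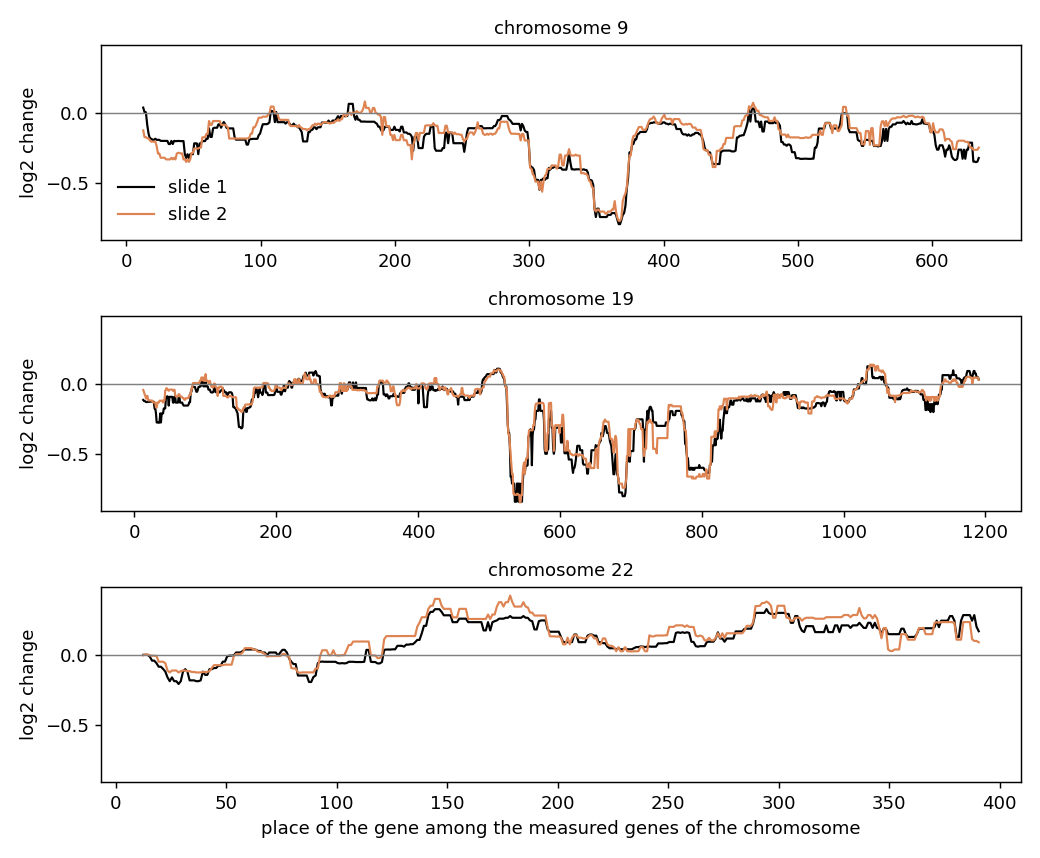
Running median over 25 consecutive measured genes of the log2 change relative to the median of all genes (y axis), along chromosomes 9, 19 and 22 in gene order (x axis), on slide 1 (black) and slide 2 (orange). Stretches of chromosomes 9 and 19 lie below -0.5 on both slides.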

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

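The tests weighed for DENND2D were chosen after its values were seen. A check of 16 sets of 4 array values for a single array far from the others picked out 4, where chance picks about 1 in 20. For the brighter DENND2D probe, vector replicate 3 had a log2 value of -3.66, far above the other vector arrays at -5.59 to -5.40. The 75th percentile of the signal was 1672 on DENND2D replicate 3 and 1823 to 1846 on the other DENND2D arrays. DENND2D replicate 1 had 110 outlier spots against 10 to 19 on the others of its group, and vector replicate 2 had 132 against 15 to 29.

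DENND2D itself was not higher in the arrays labelled DENND2D, although other genes separated the groups widely. One candidate explanation is that the probes lie outside the transfected sequence, as a probe in the untranslated end of the gene would if only the coding part was inserted. The second probe had a log2 fold change of 0.040, near background in both groups, which does not decide this without the probe and insert sequences. Exchanged group labels would make DENND2D higher in the vector-labelled arrays. The interval of the log2 fold change reached from -2.12 to 0.42 and so leaves this open, and without vector replicate 3 the value was -0.25. Loss of expression of the insert in the cells was not tested. These possibilities cannot be told apart with the arrays alone.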

How the results depend on the processing

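Scaling on spike-in spots, slide 2 alone and leaving out the shifted runs of neighbouring genes were added after the data were seen. The count of genes past the threshold, 11175, stayed within 1.5 times under all alternatives but a test against a 1.5-fold change (limma's treat), which called 1112 because it asks for a larger effect. Leaving out 1 array gave 8966 to 11100 genes. The count with at least a 2-fold change, 762, ranged from 752 to 770 with 1 array left out, and stayed within 1.5 times in all other settings. With the labelling reaction number as a replicate block, 12880 genes passed, 764 with a 2-fold change, 7 lists passed and DENND2D had a log2 fold change of -0.85; beyond the p53, interferon and TGF-beta lists and SOX2, the block changed no call of a named gene or list. DENND2D stayed negative and short of the threshold wherever it was tested, from -1.12 without vector replicate 4 to -0.25 without vector replicate 3. A filter on all 8 arrays left it out. With 1 array left out, 6 to 10 lists passed. With an estimated inter-gene correlation 0 of 36 lists passed, with 8 at the preset value. At the preset correlation, the lists of unfolded protein response, NF-kB, ribosomal protein and histone genes passed in all 24 other settings, with adjusted p up to 3.65e-06, 0.0349, 0.00694 and 0.00218. Interferon genes failed in 2 (up to 0.0783), MHC class I genes in 1 (0.0513), lysosome genes in 4 (up to 0.0882) and p53 targets in 13 (up to 0.115). TGF-beta targets passed in 9 (down to 0.0296), hypoxia genes in 6 (down to 0.000844) and G2/M genes in 1 (0.0187). Camera was not run with the labelling reaction as a random block, nor with treat.

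Of 161 other named genes, 149 kept their direction and their side of the threshold under every alternative that tested them, 0 changed direction, and 12 lost the threshold in at least 1: SOX2, CD68, BID, E2F2, CCNB2, TP63, PECAM1, H2AC16, TWIST2, HSPA6, ERG and ENG. With 1 array left out, HSPA6 did so without DENND2D replicate 3 or 4, TP63 without DENND2D replicate 1, TWIST2 without DENND2D replicate 2, PECAM1 without vector replicate 1, ERG without vector replicate 3, and SOX2 without DENND2D replicate 3 or 4 or vector replicate 4. Sizes moved by at least 1.5 times under the mean of a gene's probes for 10 of these genes and under normexp background for 20, and under no other alternative. Of 60 named genes with several probes, 44 had every probe past the threshold in the same direction and 0 had a probe past it in the other. With the mean of a gene's probes, 3 had a change smaller by at least 2-fold (log2 fold change of NTN1 from 3.45 to 1.91, MAP2 from 2.91 to 1.87 and C19orf33 from -5.16 to -4.12) and 1 a larger one (SERPINB2, from 2.81 to 4.60, above FN1 at 3.45). MMP1 went from 1.73 to 0.79. With normexp background and an offset of 50 all 20 changes were smaller, 7 of them among the 12 largest falls (IL13RA2 from -6.44 to -5.48, SUN3 from -4.59 to -3.39) and 10 among genes with only a bound, each then below its bound.

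Some lists far from the threshold turned direction, and the cause was not tested. The adjusted p values after the turn were, with quantile normalization, 0.798 for G1/S genes, 0.776 for cholesterol genes and 0.919 for fibroblast markers; with normexp background, 0.982 for cholesterol and 0.947 for KRAB genes; with the mean of a gene's probes, 0.788 for both; with every probe on its own, 0.439 for pro-apoptotic, 0.443 for cholesterol and 0.899 for KRAB genes; with 4 separate arrays, 0.889 for KRAB genes; with spike-in scaling, 0.96 for fibroblast markers; and without the shifted runs, 0.943 for mesenchymal genes. With 1 array left out, the adjusted p of the lists that turned in at least 1 case lay between 0.747 and 0.98 for KRAB genes, 0.789 and 0.963 for G1/S genes and 0.747 and 0.929 for fibroblast markers. Signal over background limits DENND2D, the 29 genes with only a bound and the largest falls.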

Other observations

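The tests on neighbouring genes, on ribosomal protein genes and on mitochondrial genes were chosen after those patterns were seen. Genes encoded in the mitochondrial genome were higher in the DENND2D-labelled arrays. All 6 that were measured passed the limma threshold. ND1 rose by a log2 fold change of 1.23 (SE 0.04, n = 3 reactions per group, adjusted p = 1.7e-05), COX1 by 0.89 (SE 0.04), CYTB by 0.78 (SE 0.04), ND3 by 0.64 (SE 0.03), ND2 by 0.57 (SE 0.03) and ND6 by 0.49 (SE 0.04). Their direction held with quantile, median, normexp and spike-in scaling.

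Whole chromosomes also differed. The median log2 fold change was lowest on chromosome 9, at -0.20, with 58 genes higher and 295 lower past the threshold, and next on chromosome 19, at -0.16, with 85 higher and 468 lower. On chromosome 8, with the highest median of 0.05, 216 were higher and 85 lower, and on chromosome 22, at 0.04, 146 were higher and 54 lower.

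Runs of neighbouring genes on chromosomes 9 and 19 were lower together. Noise of a single slide is argued against, since medians over 662 runs of 25 genes correlated between slides with r = 0.94, against at most 0.76 when genes were shuffled. Cross-hybridisation among tandem gene copies is argued against as the only source of the correlation over all placed genes. Genes 10 places apart that share no symbol stem still had a Spearman correlation of 0.14, against at most 0.02 in shuffles. At 50 places it was still 0.11, so it reflects wide stretches and does not test the low runs themselves. In 10 runs (6 on chromosome 19, 2 on chromosome 9) chosen as low by every other gene on slide 1, the genes between these were followed on slide 2. Among those sharing no symbol stem with the choosing genes, 80.9% of the dimmer (38 of 47) lay below the median of all genes. Of the brighter, 93.5% (43 of 46) did so, against 47.2% of all placed genes. Unequal gene dosage between the 2 cell populations may account for the low runs. This remains a hypothesis, since any change of a whole region would give the same, the medians differed, at -0.19 for the dimmer and -0.55 for the brighter genes, the labels name no separate RNA for each slide, gene copy number was not measured, and a regional change of chromatin was not tested. A difference between cell clones that arose apart from DENND2D stays open, as the labels do not say how many clones were used.

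By comparison with genes drawn independently, place in the genome and brightness left part of the fall of ribosomal protein genes unaccounted for in these samples. Of the 38 members 1, RPS16, lay in a low run, and the median log2 fold change of the other 37 was -0.18. This was at percentile 0.01 among 10000 random lists matched on brightness and taken outside the low runs, whose median was -0.08. Chromosomes 9 and 19, the lowest by median, held 8 of the 38 members. The 30 elsewhere had a smaller median fall, -0.14, with 14 lower and 0 higher past the threshold. Lowered chromosomes or neighbours outside the low runs also left part of the fall by this comparison. With the median of its chromosome taken from each gene, the median of the 38 members was -0.16. With that of the 24 nearest other genes it was -0.17. In both cases 0 of 10000 random lists matched on brightness were as low. Compression of the brightest signals would lower other genes of the same brightness as much. Of 10000 lists of such genes, 0 had a median as low as that of all 38 members, -0.19. The random lists drew genes independently, whereas the estimated correlation among ribosomal protein genes was 0.34. A median of genes that vary together spreads more, so these percentiles and counts are not p-values. They cannot show that the remaining fall exceeds chance. By camera with that correlation the list had an adjusted p of 0.421. No biological explanation for the fall was tested.

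With 6 labelling reactions there are 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 of the 10 with as many genes past the threshold, 11175 against at most 0 in any other. With a 2-fold change it was 762 against at most 0. Every other split mixes both groups on each side, so the group difference itself widens the spread within sides. Few calls then follow by construction, so this contrast does not measure chance. At an unadjusted limma p under 0.05 the other splits gave 102 to 2131 genes. The real split parts all 3 pairs of same-numbered reactions, as do 3 others, which also gave 0. The other 6 part 1 pair, and the 4 of these that put reaction 1 of both groups on the same side gave 932 to 2131 genes at the unadjusted threshold.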
